A study of Caenorhabditis elegans with 4 samples.

How the data were processed

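Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on late embryos of the nematode Caenorhabditis elegans, strain OP305. Per the labels, this strain has an unc-119(ed3) mutant background. It carries the transgene wgIs305, in which nhr-11, a gene of the nuclear hormone receptor family of transcription factors, is fused to TY1, EGFP and FLAG tags. The transgene was introduced by microparticle bombardment and the strain was outcrossed 3 times. Animals were hermaphrodites grown at 20 °C on E. coli HB101 and crosslinked with 2% formaldehyde, per the labels' protocols. Chromatin was sonicated, and the tagged protein was collected with anti-GFP antibodies. A part of the lysate taken before immunoprecipitation served as input, that is, total genomic DNA. The series held 4 samples, 2 ChIP and 2 input, each numbered replicate 1 or 2 in the labels. The labels do not say whether the replicates came from separate cultures, so differences between them measure only the spread between these libraries, which may be technical.

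The analysis used 3 peak lists. One list belonged to ChIP replicate 1, one to ChIP replicate 2, and one to the whole series (called the series-wide list here). Per the file headers and columns, peaks were called with PeakSeq, a caller that scores ChIP reads against a control, on genome build WormBase WS220. The version and settings of the caller, the aligner, the control used for each list and the way the series-wide list was made (pooled reads or otherwise) are not given in the sources used here. Each peak had a chromosome, a start, an end, a number in its name and 1 significance value. That value is a deposited p-value or q-value, and the files do not say which; it is called the authors' score here, and a smaller score means a stronger peak. Scores lay below 0.001 in all 3 lists. The score multiplied by the peak number never fell along the numbers (relative tolerance 1e-09). Any list sorted by score gives that, so alone it does not tell a raw from an adjusted p-value. In the series-wide list the score itself fell from number 51 (9.527e-15) to number 52 (9.524e-15). A score that falls while the product does not is the pattern of a p-value adjusted by its rank. Scores were used to rank, filter and describe peaks within a list. The lists were called separately, so a score in 1 list is not on a known common scale with a score in another. Ranks were compared between lists for regions present in all of them. Scores are shown on a −log10 scale where medians are compared. No read counts, coverage or fold enrichment were analysed here, so the sequencing depth behind each peak is unknown, and the input libraries entered only through the authors' calls.

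Coordinates are 1-based WS220 positions as listed. The gene table at hand was of another assembly, WBcel235, so none of its coordinates were used and it served only to look up the name and chromosome of nhr-11. For that reason 4 analyses planned before the data were examined were not run: distance of peaks to gene starts, enrichment of 20 gene lists, motif content of peaks, and peaks near the transgene loci. Regions are therefore named by position. The rule for naming them, fixed before the data were examined, took the 10 best-scored series-wide peaks and the next 5 best-scored peaks found in all 3 lists. Other regions named in the text were chosen after their values were seen.

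A peak was counted as shared when it overlapped a peak of the other list by at least 1 bp. Chance overlap was estimated by relocating 1 list at random within each chromosome, keeping peak widths and avoiding overlaps, in 10000 draws. These permutation tests were one-sided, and the smallest p they can give is 0.0001. Differences in median −log10 score and correlations were tested by two-sided permutation with 100000 resamples, for which the smallest p is 1e-05. Correlations used peaks that overlapped one to one. They are across peaks, which are not independent replicates. The number of peaks on each of the 6 chromosomes was compared with the chromosome's share of the genome by a two-sided exact binomial test with Benjamini-Hochberg adjustment over the 6. Chromosome lengths were taken as the end of the last peak in any list (100185410 bp in all). Shares carry 95% Wilson intervals. Intervals cover counting error only, and neighbouring peaks are not independent, so the intervals and binomial p-values are too narrow and too small to that extent.

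The alternatives fixed before the data were examined were a minimum overlap of 50% of both peaks, midpoints within 200 bp, peaks set to 400 bp, the best-scored 50% or 25% of each list, circular shifts in place of independent relocation, merging of touching peaks, and the best-scored partner for matching. They also included the peaks held by both replicates, each replicate list in turn, covered base pairs in place of peak numbers, and the outer 25% on each side as chromosome arms. Alternatives added after the data were seen left out the broad block of chromosome IV, left out series-wide peaks under 50 bp, left out stretches of wide peaks on chromosome II from the covered base pairs, or counted peaks within 10000 bp of each other once. The procedures were tested on simulated data. The relocation test called 3 of 100 pairs of unrelated lists at the 0.05 level, and 4 of 100 with circular shifts. The unrelated lists were made by the same independent relocation as in the test, so a low rate of calls was built in. They lacked the clustering of the real peaks, and the simulations used fewer draws and resamples than the main tests. The relocation test called all 100 simulated pairs that held 20 planted shared peaks. The test of medians called 20 of 20 planted differences and 6 of 100 pairs without one, and the correlation test called 7 of 100 unrelated score sets. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.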

Results

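Binding of the GFP-tagged nuclear hormone receptor NHR-11 was mapped by ChIP-seq in late embryos of C. elegans strain OP305. The series held 2 ChIP samples and 2 input samples, and 3 peak lists were examined. ChIP replicate 1 had 328 peaks with a median width of 312.5 bp, which covered 152858 bp. ChIP replicate 2 had 258 peaks with a median width of 342.5 bp, which covered 131289 bp. The series-wide list had 2836 peaks with a median width of 220 bp (interquartile range 147 to 359), and it covered 831280 bp, or 0.830% of the genome span. Peaks under 50 bp made up 9.52% of the series-wide list (270 peaks), against 8 peaks in replicate 1 and 3 in replicate 2. The strength of each peak is given by the authors' own score, a p-value or q-value for which smaller is stronger. Scores below 1e-10 were listed for 27 peaks of replicate 1, 34 of replicate 2 and 99 of the series-wide list. The read depth behind the calls is unknown.

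The best-scored peaks of the series-wide list lay on chromosomes IV, X, II, III and V of the WS220 build, and each of the 10 best was called in both replicates. The first was an 11469 bp peak at IV:9067496–9078964 (authors' score 3.44e-62). A second peak of the same neighbourhood, IV:9049732–9057089, was 7358 bp wide and had a score of 5.54e-42. The other 8 were between 683 and 1599 bp wide. Chromosome X held 5 of them. They lay at X:11605611–11606392 (8.92e-59), X:14525379–14526212 (9.24e-51), X:9187129–9188651 (1.40e-41), X:2996568–2997391 (3.58e-33) and X:11093641–11094323 (2.28e-31). Chromosome II held 1 at II:14337583–14339163 (8.62e-49), chromosome III 1 at III:7446286–7447884 (2.05e-40) and chromosome V 1 at V:3098758–3099621 (1.12e-31). The next 5 peaks found in all 3 lists were X:16928717–16930405 (7.15e-30), III:204359–205479 (1.80e-29), II:5144937–5145424 (7.53e-26), IV:9062420–9066118 (3.94e-25) and IV:2829768–2830660 (7.20e-24).

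The order of these regions differed between the lists. In the replicate lists X:9187129–9188651 was number 2 of replicate 1 and number 3 of replicate 2, and III:7446286–7447884 was number 3 and number 2. The peak at II:14337583–14339163 was number 4 in all 3 lists. For the X:9187129 and II:14337583 peaks the start and end called in the replicates differed by a summed 6 bp. The peak with the best score of both replicate lists was a different region, at the right end of chromosome I. It spanned I:15064004–15067652 in replicate 1 (3649 bp, score 2.08e-224) and I:15064003–15067646 in replicate 2 (3644 bp, score listed at 0). This region was not in the series-wide list. Background knowledge places the repeated ribosomal RNA genes at that end of chromosome I.

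The replicates answer how far the same regions were called in separate libraries. Of the 328 peaks of replicate 1, 140 (42.7%, 95% Wilson interval 37.4 to 48.1) overlapped a peak of replicate 2. Of the 258 peaks of replicate 2, 138 (53.5%, 47.4 to 59.5) overlapped a peak of replicate 1. Random relocation gave a mean of 0.825 shared peaks and at most 6 in 10000 draws (permutation p = 0.0001, the smallest these draws can give). Sharing was concentrated among the best-scored peaks. In replicate 1, 48 of the first 50 peaks (96%, 86.5 to 98.9) were found in replicate 2, then 37 of the next 50 (74%), 18 of the next 50 (36%) and 11 of the 50 ranked 251 to 300 (22%, 12.8 to 35.2). In replicate 2, all 50 of the first 50 peaks were found in replicate 1 (100%, 92.9 to 100), followed by 36 (72%), 24 (48%), 16 (32%) and 12 (24%) in the following bins of 50. The 8 peaks ranked 251 to 258 of replicate 2 included 0 shared peaks, for which the interval reached 32.4%. The 2 peaks among the first 50 of replicate 1 that replicate 2 lacked were X:16931251–16931801 (score 6.84e-09) and X:4709532–4710165 (5.18e-08), both of which were in the series-wide list. Shared peaks were wider, with a median of 395 bp against 274.5 bp for unshared peaks in replicate 1, and 411.5 bp against 276.5 bp in replicate 2.

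**Figure D1:**
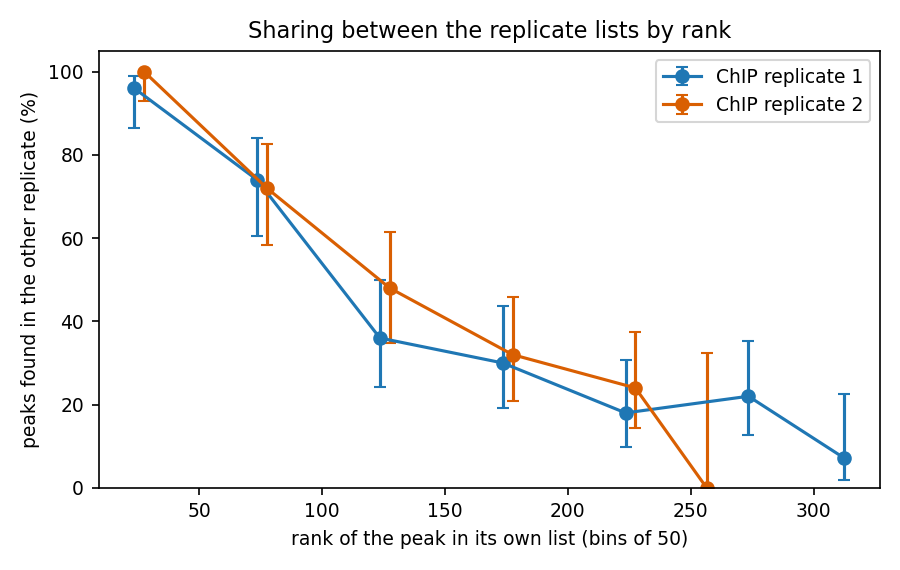
Share of peaks found in the other replicate list (percent, y axis) for bins of 50 peaks ranked by the authors' score (x axis), with 95% Wilson intervals as bars. Nearly all of the first 50 peaks were shared (96% in replicate 1 and 100% in replicate 2), and 24% or less of those ranked above 200 were.

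Peaks that were strong in 1 replicate list also tended to be strong in the other. Over the 136 regions that matched one to one, the scores had a Spearman rho of 0.697 (permutation p = 1e-05, the smallest the resamples can give). Pearson's r of the −log10 scores was 0.932 over 135 regions (permutation p = 1e-05), leaving out the region whose score was listed at 0. These are correlations across regions within 1 pair of libraries, and regions are not independent replicates.

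**Figure D2:**
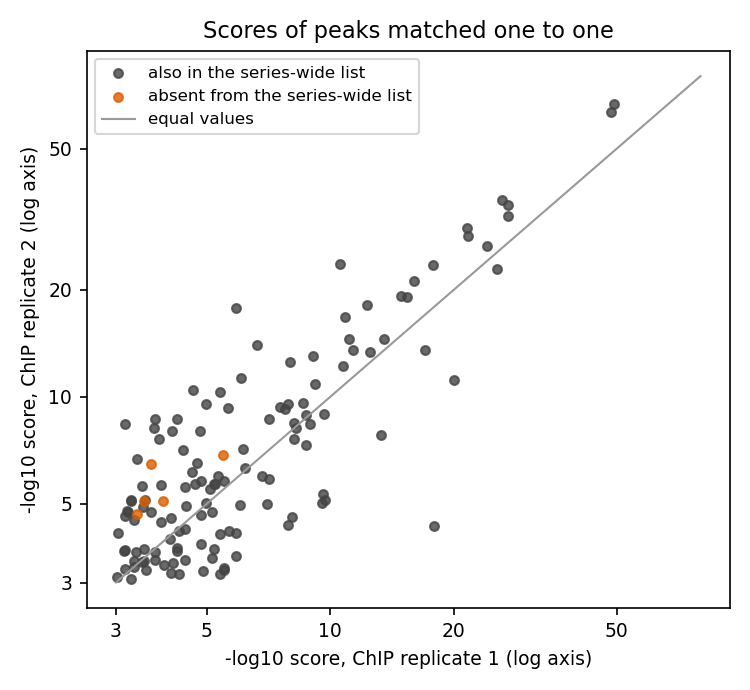
Authors' scores (−log10, log axes) of regions matched one to one between ChIP replicate 1 (x axis) and ChIP replicate 2 (y axis), with the line of equal values. The 135 regions with a score above 0 are drawn (Spearman rho 0.697 over all 136), and regions absent from the series-wide list are in orange.

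The series-wide list contained nearly all peaks of the replicate lists and many more. It held 311 of the 328 replicate 1 peaks (94.8%, 91.9 to 96.7) and 247 of the 258 replicate 2 peaks (95.7%, 92.5 to 97.6), where relocation gave means of 7.10 and 5.80. In the other direction, 424 of its 2836 peaks (15%, 13.7 to 16.3) overlapped a peak of either replicate list, against a relocation mean of 9.65. All 3 permutation tests, like that of the replicate overlap, gave the smallest possible p of 0.0001, which Benjamini-Hochberg adjustment over the 4 left at 0.0001. If the series-wide list drew on the same reads as the replicate lists, overlap above the relocation means would follow by construction in these 3 tests. Relocation also placed peaks evenly along a chromosome, so the tests reject only such even placement. Both replicate lists held 133 of the series-wide peaks (4.69%), replicate 1 alone held 177 (6.24%), replicate 2 alone held 114 (4.02%), and neither held 2412 (85.0%). The share of 15% was 8.71% with the list of replicate 2 by itself and 10.9% with that of replicate 1 by itself.

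Series-wide peaks called in both replicates were stronger and wider than the rest of that list. Their median −log10 score was 11.4, against 3.57 for peaks in neither replicate list. The difference in medians was 7.79 (permutation p = 1e-05). With only 1 replicate list used, all peaks in that list, including those in both, were set against all other series-wide peaks. The difference was then 4.29 for replicate 2 (247 against 2589 peaks) and 3.75 for replicate 1 (310 against 2526 peaks). How the series-wide list was made is not given in the sources used here, and if it drew on the same reads, its peaks would not be independent of the replicate lists and a better score of shared peaks would follow by construction. The median was 5.92 for peaks in replicate 1 alone and 5.94 for peaks in replicate 2 alone. Median widths were 514 bp for peaks in both lists, 324 and 327 bp for peaks in replicate 1 or replicate 2 alone, and 202.5 bp for peaks in neither. Of the 270 peaks under 50 bp, 264 were in neither replicate list. Among the first 250 series-wide peaks, 219 (87.6%, 82.9 to 91.1) were in a replicate list, and 93 (37.2%, 31.4 to 43.3), 39 (15.6%) and 28 (11.2%) were in the following bins of 250. Of the first 100, 84 were in both replicate lists and 4 were in neither. The 4 exceptions, named after their values were seen, were I:2276575–2277699 (score 9.53e-15), II:65660–67094 (9.52e-15), II:10201978–10205205 (9.65e-13) and IV:10821758–10822566 (3.05e-11).

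Chromosome IV held fewer peaks than its length would give, and chromosomes III, I and X held more. The expected numbers are shares of the same total, so the deficit of IV by itself raises the ratios of all other chromosomes. Part of the excess on III, I and X follows from this, and a deficit of II is understated by it. The p-values of III, I and X therefore do not test an excess over the chromosomes other than IV. Whether any of them exceeds the other chromosomes with IV left out was not tested. In the series-wide list, chromosome IV had 228 peaks where 495 were expected from its length, a ratio of 0.460 (0.406 to 0.521, exact binomial test, adjusted p = 1.38e-46). Its density was 13 peaks per Mb, against 35.6 on III, 34 on I, 33.1 on X, 30.2 on V and 25.5 on II. The densities of the other chromosomes do not depend on the number on IV. Those of III, I and X lay above those of V and II, a difference that was not tested. The ratio of observed to expected peaks was 1.26 on III (491 peaks, adjusted exact p = 3.05e-07), 1.20 on I (512 peaks, adjusted exact p = 2.27e-05) and 1.17 on X (585 peaks, adjusted exact p = 6.46e-05). Chromosome II was lower, at 0.902 (390 peaks, adjusted exact p = 0.0338). Its ratio did not pass the test in the best-scored 50% of the list (0.962, adjusted exact p = 0.695), and it turned to 1.29 in covered base pairs. Chromosome IV was low in the best-scored 50% too (0.464), which raised the ratio of II there. Chromosome V did not pass the test at 1.07 (630 peaks, adjusted exact p = 0.0752).

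The replicate lists showed the deficit of chromosome IV on their own. Replicate 1 had 11 peaks there, a ratio of 0.192 (0.108 to 0.338, adjusted exact p = 2.79e-14), and replicate 2 had 14, a ratio of 0.311 (0.187 to 0.510, adjusted exact p = 8.65e-08). Chromosome III was higher in both, at 1.44 in replicate 1 (adjusted exact p = 0.00450) and 1.41 in replicate 2 (adjusted exact p = 0.0337). Chromosome X was higher in replicate 1 at 1.52 (adjusted exact p = 0.00010), and its ratio of 1.30 in replicate 2 did not pass the test (adjusted exact p = 0.0667). Chromosome I did not pass it in replicate 1 (0.932) or replicate 2 (1.08), and chromosome II passed it in replicate 1 (0.700, adjusted exact p = 0.0314) but not in replicate 2 (0.992). No chromosome's share differed between the 2 replicates by Fisher's exact test (lowest adjusted p = 0.438). That test takes the lists as independent, while 140 peaks of replicate 1 overlapped peaks of replicate 2, so it leans towards no difference. Among the series-wide peaks held by both replicates, the ratio was 0.431 on IV (10 peaks, adjusted exact p = 0.00782) and 1.58 on X (37 peaks, adjusted exact p = 0.0123), and no other chromosome passed the test. The 10 peaks on IV include those of the broad block described below that both replicates called. For this set the ratio without the block was not computed. In these sets too, the low number on IV by itself raises the ratios of the other chromosomes.

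**Figure D3:**
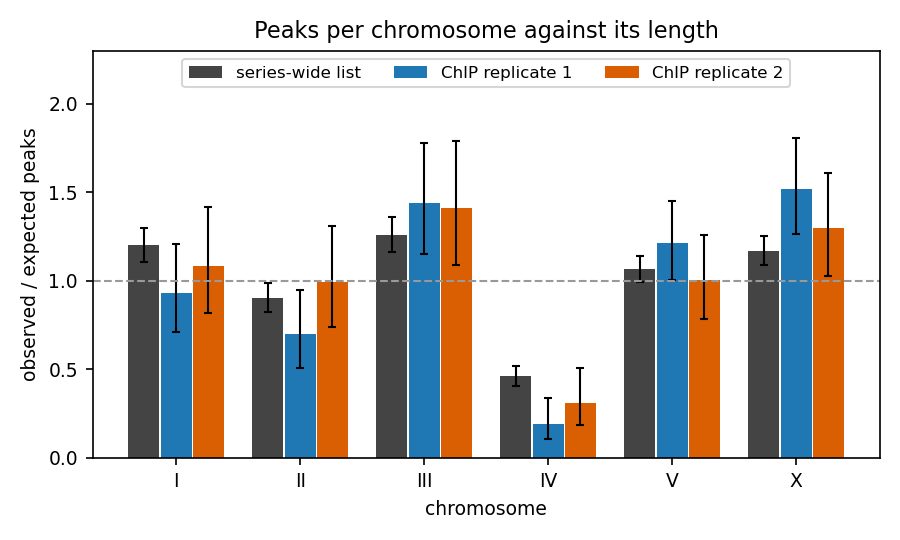
Observed peaks divided by the number expected from chromosome length (y axis) for each chromosome (x axis) in the 3 lists, with 95% Wilson intervals as bars and a dashed line at a ratio of 1. Chromosome IV is low in each list (0.460, 0.192 and 0.311), and chromosome III is above 1 in each (1.26, 1.44 and 1.41). The low number on IV by itself raises the ratios of the other chromosomes.

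Along the autosomes, peaks were spread over centres and arms. The central 33.3% of each autosome held 766 of the 2251 autosomal series-wide peaks (34%, 32.1 to 36.0), which did not pass the exact binomial test (p = 0.488). With the outer 25% on each side taken as arms, the central 50% held 52.3% of the peaks (exact binomial p = 0.0284).

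The widest peaks of the replicate lists formed 1 block on chromosome IV. The block spanned IV:9046969–9078951 in replicate 1 and IV:9046969–9078961 in replicate 2, with 5 peaks in each. In the series-wide list it had 7 peaks and spanned IV:9045762–9078964 (33203 bp), of which 75.9% was covered by peaks and the largest gap was 5330 bp. Its 11469 bp peak was called at 11389 bp in replicate 1 (score 3.06e-26) and 11423 bp in replicate 2 (1.18e-23). The 7358 bp peak was called at 7340 bp (9.29e-21) and 7237 bp (7.26e-12). The peak at IV:9062420–9066118, 3699 bp wide, was called at 3667 bp (6.70e-09) and 3695 bp (2.59e-08). The 3 widest peaks of each replicate list lay in this block. In the series-wide list 2 of the 3 widest did. The widest peak outside the block was 5620 bp in the series-wide list, 3649 bp in replicate 1 and 3644 bp in replicate 2, the last 2 being the peak at the right end of chromosome I. The remaining best-scored peaks had a median width of 785 bp in the series-wide list, 654 bp in replicate 1 and 645 bp in replicate 2 among those of the first 50 peaks that lay outside the block. The strain carries tagged nhr-11 as a transgene, and the WBcel235 gene table lists nhr-11 (CELE_ZC410.1) on chromosome IV. Its position was not compared with these WS220 peaks. Outside the block, chromosome IV had 221 series-wide peaks, 6 peaks of replicate 1 and 9 of replicate 2, with ratios of 0.447, 0.106 and 0.204.

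**Figure D4:**
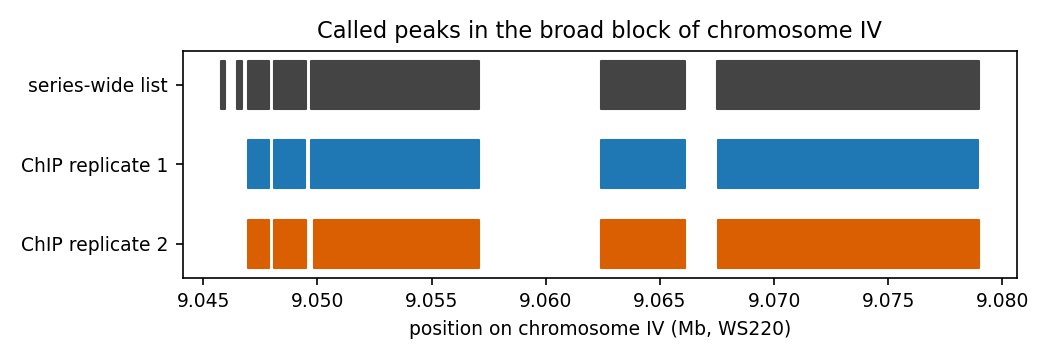
Called peaks of the 3 lists (rows) along the broad block of chromosome IV (x axis, position in Mb, WS220), drawn to scale. The outer ends of the block differ by at most 10 bp between the replicates, and the series-wide list adds peaks at its left end.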

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

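Alternatives that left out the broad block, peaks under 50 bp or stretches of wide peaks on chromosome II, or that counted peaks within 10000 bp once, were chosen after the data were seen. Of the alternative values, 84 kept their direction and their side of the threshold, or stayed within the interval of the main value, and 21 did not. The 84 include 11 values from merging touching peaks, which changed nothing because no peaks of a list touched or overlapped. Also among the 84 were all alternatives of the replicate overlap (36.6% to 59.8%), of the replicate 1 peaks (82.0% to 94.8%) and replicate 2 peaks (83.3% to 95.7%) in the series-wide list, of the series-wide peaks in either replicate list (8.71% to 16.3%, of which 8.71% and 10.9% with 1 replicate list), of the difference in median score (3.18 to 7.99, of which 4.29 and 3.75 with 1 replicate list) and of the score correlation (rho 0.664 to 0.744). The best-scored 50% of each list held 1418, 164 and 129 peaks, by construction. In the best-scored 50%, where the low number on IV also raised the ratio of II, the deficit of chromosome II no longer passed the test (0.962). With peaks held by both replicates, chromosome I reversed (0.950), and II (0.789) and III (1.20) no longer passed; this set is far smaller. In the replicate lists, taken without replicate 1 or without replicate 2, the ratios were 0.932 to 1.08 on I, 0.700 to 0.992 on II and 1.30 to 1.52 on X, and the call was lost in both lists on I and in the list of replicate 2 on II and X. In covered base pairs, which has no test, II reversed (1.29) and V fell below 1 (0.949), while I (1.08), III (1.13), IV (0.625) and X (1.02) moved towards 1. The pair of stretches of wide peaks on II held 44.1 kb of its covered length, and without them II was at 0.991 and V at 1.002, so those stretches account for the reversal of II. Without them I (1.14), III (1.19) and V lay within the interval of their main ratio, while II, IV (0.660) and X (1.08) did not. On IV the broad block held 25203 of the 90744 covered bp, which raised the ratio of IV in this measure. A ratio without the block was not computed, and what else moved II, IV and X was not tested. With the outer 25% on each side as arms, the central share (52.3%) passed the test; the cause was not tested. The deficit of chromosome IV stayed past the threshold under all 7 alternatives with a test, merging included (0.192 to 0.548). No paired analysis was possible because the input samples have no peak list here, so ChIP and input could not be compared by replicate number. Alternatives for the gene start, gene list, motif and transgene analyses were not run, since no annotation or genome of WS220 was used here. Read depth is unknown, so its effect on the weak, unshared peaks cannot be given.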

Other observations

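The tests of clustering, of wide peaks, of the broad block and of the regions absent from the series-wide list were chosen only after those results were seen. Peaks lay closer together than random relocation gave. In the series-wide list 267 peaks (9.41%) had a neighbour within 1 kb, 1.59-fold the random mean of 168. In the replicate lists 23 and 21 peaks did, which was 8.99-fold and 14.2-fold the random mean. Within 100 kb of the left end of a chromosome lay 48 series-wide peaks (2.81-fold), 6 peaks of replicate 1 (3.05-fold) and 4 of replicate 2 (2.57-fold). Right ends were left out, since chromosome lengths were set by the last peak. Of these 6 permutation tests, 5 passed after Benjamini-Hochberg adjustment (highest adjusted p = 0.0186), and that of left ends in replicate 2 did not (adjusted p = 0.0679). A peak at the right end of chromosome III, III:13778124–13781292 (3169 bp, score 2.12e-10), was called in all 3 lists.

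Chromosome II held 15 of the 23 series-wide peaks of at least 1500 bp outside the broad block of chromosome IV, and 13 of the 15 were in neither replicate list. The exceptions to a gathering in a pair of stretches were II:10548174–10549809, in neither replicate list, and II:14337583–14339163, in both. From 2012829 to 2143804 (131 kb), 7 of 9 peaks were that wide, the widest reached 5620 bp, and peaks covered 18.2% of the stretch. The best score there was 1.42e-06, and 1 of the 9 peaks was in a replicate list. From 9986203 to 10205205 (219 kb), 6 of 21 peaks were that wide, the best score was 9.65e-13, and 3 of the 21 were in a replicate list.

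Chromosome IV held few peaks at every level of strength. Outside the broad block it had 51, 58, 53 and 59 peaks in 4 successive groups of 707 series-wide peaks ranked by score. Absent peak numbers do not account for it: 33 are absent from the series-wide list, and with all of them placed on IV the ratio was 0.521 (0.464 to 0.584). Peaks lost before numbering or past the highest number would leave no absent number, so this check cannot exclude such a loss. A stricter significance scale for IV might remove its weak peaks first, but the odds ratio of IV in the best against the worst of these groups was 0.854 (0.566 to 1.29, Fisher's exact p = 0.487). That test cannot exclude such a scale, since a common shift of all scores on IV could leave their distribution unchanged, and no biological explanation was tested.

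The block of wide peaks on chromosome IV might reflect extra copies of the tagged nhr-11 fragment carried by the strain, which would raise read numbers along the whole fragment. Its outer ends differed by at most 10 bp between the replicates, as a fixed DNA fragment would give. Inside the block lay an uncalled gap of 5330, 5356 and 5336 bp in the series-wide list, replicate 1 and replicate 2, with 75.9% to 77.2% of the block covered. Read numbers in the gap were not analysed, so the gap does not decide for or against copies along a whole fragment. The same ends could arise from binding along a broad domain called against the same input. Copies and binding cannot be told apart, as the input libraries, in which copies would also appear, and the position of nhr-11 in WS220 were not analysed here, and no biological explanation was tested.

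Of the 136 regions matched one to one between the replicates, 6 were absent from the series-wide list. Besides I:15064004–15067652 these were X:293241–293626, III:1301535–1301908, II:3994525–3994976, I:10217820–10218201 and X:11787102–11787545 (positions of replicate 1). Their summed start and end differences between the replicates were 1 to 7 bp (median 2.5), all 6 within 10 bp, against 16 of the 130 regions in all 3 lists (12.3%). Removal of peaks after numbering stays open for all 6, as 33 numbers are absent. The lowest of them, 476, is far from the place of the chromosome I region as number 1 of both replicate lists. A rule set after the results were seen counted a lowest absent number this high against removal of that region. Of the 36 matched regions in the first 50 of both replicates that the series-wide list held, 33 had a series-wide number below 476. The other 3 did not. V:264907–265849, number 26 of replicate 1 and 29 of replicate 2, was number 581. III:10224450–10225340, number 25 and 20, was number 1045, and V:18400225–18400690, number 48 and 38, was number 1540. None of these 3 stood near number 1 of a replicate list, so removal is least supported for the chromosome I region, though a single region cannot settle it. A different control for the series-wide list is a candidate explanation: when the 130 regions were ranked within each list, places gained in the series-wide list rose with the end difference (Spearman rho 0.298, permutation p = 0.0005; Pearson's r 0.351, permutation p = 0.00015). Given the rank in the replicates, rho was 0.215 (permutation p = 0.0138). The controls are unknown and this relation does not measure them. It cannot tell a different control from another way of making the series-wide list, such as pooled reads. The same relation in differences of −log10 score (rho 0.264) was set aside, as the lists share no known scale. Regions are not independent replicates, and no biological explanation was tested.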
